A study of Homo sapiens with 8 samples.

How the data were processed

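The series holds 8 samples of human primary PAEC in 4 groups of 2: p53 ChIP after doxorubicin, p53 ChIP after PBS, and the input DNA of each. Per the labels' protocols, cells were treated for 24 h, fixed with 1% formaldehyde for 10 min, and their chromatin was sheared by sonication before sequencing libraries were made. The 4 ChIP samples were used. The inputs were not analysed here, and how they entered the peak calling is not given in the sources used here.

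Reads were aligned with BWA to hg19 and peaks were called with MACS2, per the submitters' processing notes, which give no versions or options. The authors deposited 4 lists of summits, called in each library alone, and 2 tables of regions matched between the replicates of a treatment by an irreproducible discovery rate analysis. In the summit lists each entry is 1 bp wide, and the deposited score is a −log10 q-value, read from the values, whose minimum was 1.32 or more in each list, and from the file's stated FDR of 0.05. In the deposited tables of matched regions, each region has a −log10 p-value per replicate, per the file headers a signal value 1 and 2. That unit was inferred from the minimum of 2.01, which is a p near 0.01, and from a nearly constant excess over the −log10 q of the summit in the same region (median 3.63 to 4.57 by library). The IDR is a fraction from 0 to 1, per the file headers. The deposited tables were not filtered on it, since it reached 0.536 with doxorubicin and 0.264 with PBS. All matched regions were therefore the main list, and the subset at IDR at or under 0.05 was added after seeing the data.

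Chromosome Y, the mitochondrial genome and 72 to 74 Mb of chromosome X were left out of every list. Positions are hg19, with starts taken as counted from 0 in the deposited files and written here counted from 1. No p-value or score was compared between lists, because scores grow with read depth, which is not given in the sources used here. Depth therefore limits every count of summits or regions, and a region missing from a list was not detected there, which is different from not bound.

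Summits per library were compared with an exact two-sided permutation test of the group means over the 6 ways of assigning 2 of 4 libraries. Replicate lists were compared by the share of the shorter list with a summit of the other list within 200 bp. The plan had asked for 1 bp of overlap between peaks, which for 1 bp summits requires the same base, so the distance was used in its place. Treatments were compared by regions sharing 1 bp or more. Chance overlap came from 1000 circular shifts of the regions within chromosomes (100 for other definitions of overlap), with a one-sided p. The shifts took no account of which sequence can be mapped or is accessible. Overlap above them shows that positions recur, and does not by itself show shared p53 binding. Ranks were compared by Spearman correlation with two-sided p from 100000 permutations. Shares carry Wilson 95% intervals, which cover counting error only. Means of a score or share over 2 libraries carry the SD. Regions were ordered by the mean −log10 p of both replicates and split into 10 groups of nearly equal number. The overlap code was tested on 1 simulated list of 1000 regions, set against the doxorubicin list. The 300 planted overlaps, slightly moved copies of doxorubicin regions, were recovered at 100%, and 0.143% of the 700 random ones overlapped. This checks the code only.

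The regions named were fixed by rule before the data were examined: the 10 strongest doxorubicin regions with summits in both replicates, the 5 strongest PBS regions, and the 5 strongest PBS regions with no doxorubicin region. The strongest 5 doxorubicin regions with no PBS region were added after their values were seen. A further part of the rule named genes from 18 fixed gene lists, on p53 targets, endothelial and vascular genes and markers of other cell types. No genome or annotation of hg19 was used here, so the tests of gene lists, the promoter share and the p53 motif share were not made, and regions are given by position without a gene.

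Alternatives were a stricter q of 0.01, merging summits within 500 bp, autosomes alone, 50% reciprocal overlap, centres within 200 bp, the better-scoring 50% of each list, summits found in both replicates in place of matched regions, a doxorubicin list of PBS length, each replicate left out, and the replicate number as a block. Stricter IDR limits, lists without clusters, other cluster definitions, summits within 500 bp or at the same base, and all settings tried for the strength groups, the PBS summits in doxorubicin regions, the chromosome shares and the named regions were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.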

Results

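Binding of p53 to chromatin was mapped by ChIP-seq in human primary pulmonary arterial endothelial cells (PAEC), the cells that line the arteries of the lung. The cells were exposed for 24 h to doxorubicin at 0.5 µg/ml or to PBS, its vehicle. Doxorubicin is an anthracycline that traps topoisomerase on DNA and breaks it, and p53 is the transcription factor that is stabilised after such damage. The series asks which sites p53 occupies in the pulmonary endothelium under genotoxic stress. Each treatment had 2 p53 ChIP samples, replicate 1 at passage 3 and replicate 2 at passage 5. The 4 input DNA samples were not analysed here. The labels do not say whether the replicates came from separate cultures or donors beyond the passage, so the spread between them may be technical. The number of reads per library is not given in the sources used here, and the number of summits a library yields depends on it.

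Doxorubicin-treated PAEC had more p53 summits than PBS-treated PAEC in both replicates. At an FDR under 0.05, the doxorubicin libraries held 2833 summits in replicate 1 and 9758 in replicate 2, and the PBS libraries held 687 and 723. The group means were 6295.5 ± 4896.71 summits with doxorubicin and 705 ± 25.5 with PBS (SD, n = 2 each), an 8.93-fold difference. The exact two-sided permutation test gave p = 0.333, which is the smallest value this test can give for 2 libraries against 2. Replicate 1 alone gave a ratio of 4.12 and replicate 2 alone a ratio of 13.5, because replicate 2 with doxorubicin had 3.44 times as many summits as replicate 1.

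**Figure D1:**
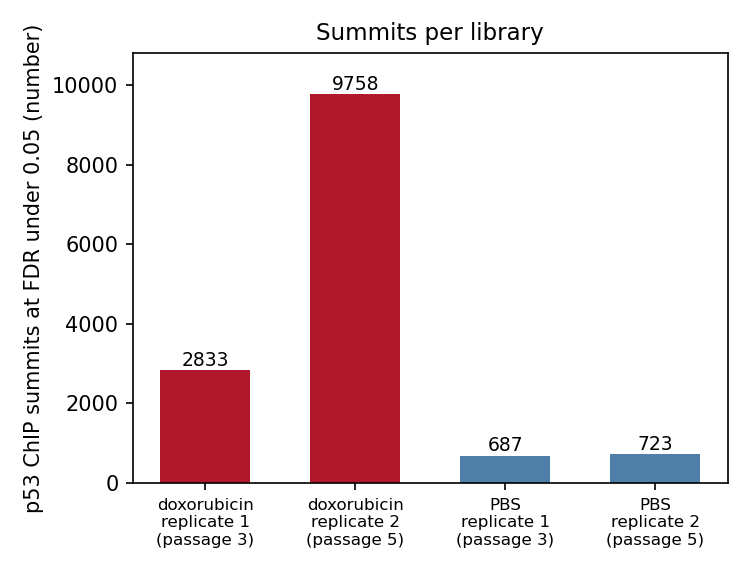
Number of p53 ChIP summits at an FDR under 0.05 in each of the 4 libraries, as bars from 0, with doxorubicin in red and PBS in blue. Both doxorubicin libraries (2833 and 9758) lie above both PBS libraries (687 and 723), and the doxorubicin libraries differ from each other more than the PBS libraries do.

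Most sites of the shorter replicate list were found again in the longer one. Of the 2833 summits of doxorubicin replicate 1, 2364 (83.4%, Wilson 95% interval 82.0 to 84.8%) had a replicate 2 summit within 200 bp, and these made up 24.2% of the longer replicate 2 list. Of the 687 summits of PBS replicate 1, 540 (78.6%, 75.4 to 81.5%) had a replicate 2 summit within 200 bp, which was 74.7% of the replicate 2 list. Random placement of the same summits gave a mean of 0.145% with doxorubicin and 0.010% with PBS. In neither treatment did any of the 1000 placements reach the observed share (permutation p = 9.99e-04, the smallest they can give). Across the 7601 regions matched between the doxorubicin replicates, the authors' −log10 p-values were ranked alike, with a Spearman rho of 0.69. Across the 1225 regions matched between the PBS replicates rho was 0.85. Both correlations are across regions, which are not independent replicates. Each had a permutation p = 1.00e-05, the smallest that 100000 resamples can give, and adjustment over the 2 correlations by Benjamini-Hochberg left both at that value.

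Most regions matched between the PBS replicates were also found with doxorubicin, while few of the matched doxorubicin regions, a far longer list, were found in PBS. Of the 1225 matched PBS regions, 947 (77.3%, 74.9 to 79.6%) overlapped a matched doxorubicin region, against a mean of 0.320% for random placements (permutation p = 9.99e-04 from 1000 placements, the smallest they can give). Of the 7601 matched doxorubicin regions, 945 (12.4%, 11.7 to 13.2%) overlapped a PBS region, and 6656 did not. Overlaps were nearly 1 to 1, so the 1225 PBS regions could reach only a minority of the 7601. These lists were not filtered on the irreproducible discovery rate (IDR), and the matched PBS list was longer than either PBS summit list (687 and 723). Of the 947 PBS regions found with doxorubicin, 257 held no summit at an FDR under 0.05 in either PBS library. At an IDR at or under 0.05, 2583 doxorubicin regions (34.0% of the list) and 783 PBS regions (63.9%) remained. The 2 shares were then 24.1% of the doxorubicin regions and 79.7% of the PBS regions. The share of doxorubicin regions found in PBS moved with the length of the lists. It was 6.68% with the summits of replicate 2 alone, 22.5% with those of replicate 1 alone, and 62.3% when the doxorubicin list was shortened to its 1225 strongest regions. At that equal length, 62.6% of the PBS regions were found with doxorubicin.

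The 10 strongest doxorubicin regions, by the mean −log10 p of both replicates, lay on chromosomes 1, 4, 7, 8, 10, 17, 19 and 21 (hg19). All 10 held a summit in both doxorubicin libraries and in PBS replicate 2, 8 also in PBS replicate 1, and 9 overlapped a matched PBS region. The strongest was chr10:45932546-45934772, with a mean −log10 p of 527.7 ± 5.25 (SD, n = 2). It contained the PBS region chr10:45933751-45934442, which ranked 215 of the 1225 PBS regions. Next came chr17:37202086-37203759, at 524.2 ± 51.2, whose PBS region chr17:37202687-37203736 ranked 39 in the PBS list. The regions chr21:34738790-34740189 (500.3 ± 85.1) and chr8:8219652-8221127 (494.6 ± 76.0) overlapped the PBS regions ranked 101 and 36. The region chr1:10803805-10805868 (491.2 ± 15.4) overlapped a PBS region ranked 566, with a summit in PBS replicate 2 and none in PBS replicate 1. The 1 region of the 10 with no matched PBS region was chr19:42422814-42425478 (464.8 ± 36.0), which held a summit of PBS replicate 2. The other 4 were chr7:121150744-121152081, chr4:84091824-84092811, chr17:67603116-67604053 and chr1:9241166-9243385. The −log10 p-values are the authors' and order regions within a list only, since neither they nor ranks in lists of different length measure a change in binding.

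The 5 strongest PBS regions were all found with doxorubicin, in matched regions and in the summits of both libraries. They were chr6:151177705-151179178 (mean −log10 p 561.7 ± 76.9, SD, n = 2), chr19:46636386-46637722 (485.1 ± 29.1), chr8:29627872-29629044 (483.3 ± 10.5), chr7:40756657-40757481 (463.4 ± 34.3) and chr3:178787219-178788659 (433.4 ± 1.61). Their doxorubicin regions ranked 12, 38, 11, 37 and 51 of 7601. Of the 100 strongest PBS regions, 100 overlapped a doxorubicin region, and of the 100 strongest doxorubicin regions, 95 overlapped a PBS region.

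Weaker doxorubicin regions were found in PBS less often than stronger ones. When each list was split by strength into 10 groups, 602 of the 760 regions in group 1, the strongest (79.2%, 76.2 to 81.9%), were found in PBS. Group 2 gave 30.1%, group 3 gave 8.03%, and each of the remaining 7 gave 3.55% or less. By the IDR, the weaker doxorubicin groups matched poorly between the doxorubicin replicates. Strength and IDR come from the same 2 replicates, so they are not independent. The median IDR of the doxorubicin groups rose from 7.40e-06 in group 1 to 0.0464 in group 4, and from 0.173 in group 5 to 0.402 in group 10. The low shares in groups 5 to 10 therefore do not show weak sites specific to doxorubicin. In the PBS list the highest median IDR of a group was 0.113, in group 9. In the PBS list, 122 of the 122 regions of group 1 were found with doxorubicin. The share was lower in groups 3 and 4, at 74.6% and 73.2%, was 93.5% in group 6, and was 25.2% in group 10, the weakest.

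**Figure D2:**
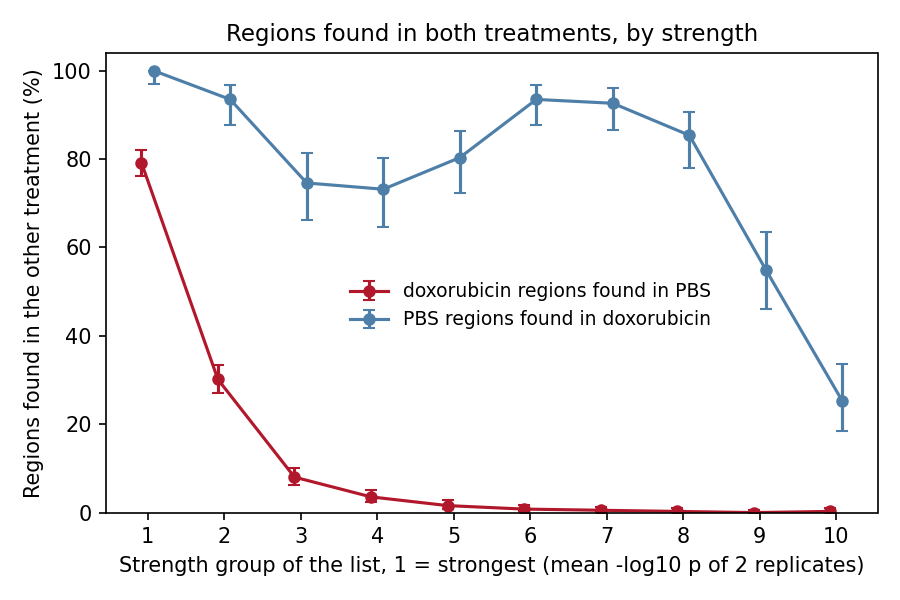
Share of matched regions that overlap a region of the other treatment, in percent, by strength group of each list in order of mean −log10 p (group 1 is the strongest of 10). Points are shares and bars Wilson 95% intervals, in red for doxorubicin regions found in PBS, which fall from 79.2% in group 1 to 0.789% in group 6. Blue is for PBS regions found with doxorubicin, which dip to 73.2% in group 4 and are lowest in group 10, at 25.2%. The median IDR of the doxorubicin groups was 0.173 in group 5 and 0.402 in group 10.

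Among the 2583 doxorubicin regions at an IDR at or under 0.05, called reproducible here, 1685 (65.2%, 63.4 to 67.0%) overlapped no matched PBS region of any IDR. The PBS list held only 1225 regions, so many of the 2583 had to lack one. Summits of the doxorubicin libraries lay in 84.3% and 98.5% of the 2583 (mean 91.4 ± 10.0%, SD, n = 2). PBS summits lay in 21.5% in replicate 1 and 24.97% in replicate 2 (23.2 ± 2.46%, n = 2), so each PBS library was below each doxorubicin library by more than either spread. The regions were chosen on the doxorubicin libraries, which raises the doxorubicin shares, and no p-value is given for this difference. For the 783 reproducible PBS regions, chosen on the PBS libraries, doxorubicin summits lay in 84.8% and 80.5% (82.6 ± 3.07%) and PBS summits in 71.8% and 72.9% (72.3 ± 0.813%). The strongest doxorubicin regions with no matched PBS region, named after their values were seen, were chr19:42422814-42425478, chr12:16089204-16090519, chr10:702729-704651, chr2:1492383-1493821 and chr2:239360865-239362940. They ranked 7, 14, 24, 42 and 58 of 7601. The first and the last held 1 summit of PBS replicate 2, and the other 3 held no PBS summit.

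The 278 PBS regions with no doxorubicin region were often packed close together. A cluster was defined, after the positions had been seen, as 3 or more PBS regions each within 50 kb of the next, which gave 23 clusters with 128 regions. Clusters held 111 of the 278 PBS-only regions (39.9%, 34.3 to 45.8%) and 17 of the 947 shared ones (1.80%, 1.12 to 2.86%), an odds ratio of 36.4 (two-sided Fisher's exact test, p = 1.57e-61, with neighbouring regions counted as independent, which makes p too small). Those with the most PBS regions were chr2:92281152-92326065, with 15 PBS regions, chr10:42384314-42408465, with 12, and chr16:46387905-46433654, with 9. None of their regions overlapped a matched doxorubicin region, yet doxorubicin replicate 1 had 14, 10 and 32 summits in them and doxorubicin replicate 2 had 0 in each. By contrast, all 4 regions of the cluster chr6:36634768-36650790 and all 3 in each of chr19:18475190-18497232 and chr4:78254002-78265561 were shared, with summits in all 4 libraries. The clusters held 106 summits of PBS replicate 1 (15.4% of its list) and 47 of PBS replicate 2 (6.50%). They held 103 of doxorubicin replicate 1 (3.64%) and 12 of doxorubicin replicate 2 (0.123%). The numbers in the replicate 1 libraries were thus close, and their shares differ because the doxorubicin list is longer. Without the clusters, 84.8% of PBS regions were found with doxorubicin.

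**Figure D3:**
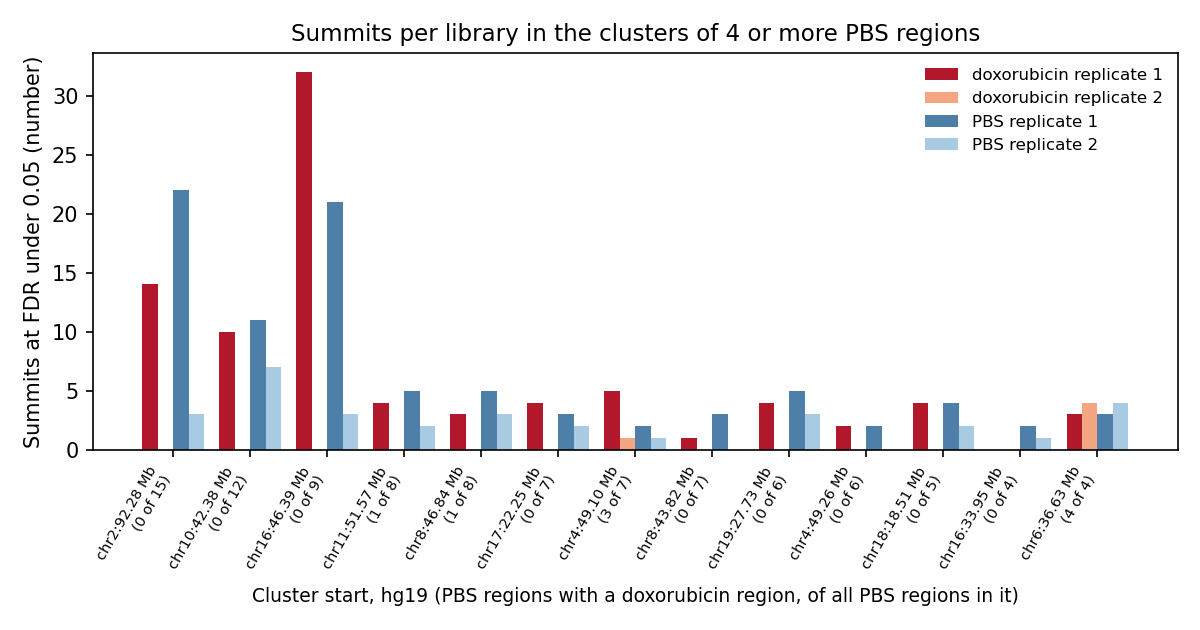
Number of p53 ChIP summits at an FDR under 0.05 per library in the 13 clusters of 4 or more PBS regions, as bars from 0, with the start of each cluster (hg19, Mb) and the number of its PBS regions found with doxorubicin below it. Doxorubicin replicate 1 (dark red) and PBS replicate 1 (dark blue) rise together at chr2, chr10 and chr16, where doxorubicin replicate 2 (light red) has 0 summits, and all 4 libraries have 3 or 4 summits in the cluster on chr6.

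The 5 strongest PBS regions with no doxorubicin region were chr10:42527849-42528222, chr10:42529136-42529637, chr17:22252978-22253425, chr7:61970208-61970581 and chr10:42393616-42393965, with mean −log10 p from 52.8 ± 7.64 to 45.4 ± 17.6 (SD, n = 2). All 5 lay in clusters, and each held a summit of doxorubicin replicate 1 and none of doxorubicin replicate 2. No hg19 annotation was used, so the kind of sequence at these regions and in the clusters was not examined. They are ChIP calls, and p53 binding at them is not shown.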

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

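Stricter IDR limits, lists without clusters, other cluster definitions and other summit distances were chosen after the results were seen, as were all settings tried for group 1 by strength, for the PBS summits in doxorubicin regions, for the clustered share and for the named regions. The excess of summits with doxorubicin kept its direction under each setting tried: 8.71-fold at q at or under 0.01, 8.90-fold with summits within 500 bp merged, 8.99-fold on autosomes, and 4.12 to 13.5-fold with each replicate left out, which leaves 1 library per treatment and no test. With the replicate number as a replicate block, the geometric mean of the ratios within a number was 7.46-fold. The numbers share a passage in the labels, and with 2 pairs no check of pairing was possible. The numbers of matched regions fell as the lists were shortened by construction. Doxorubicin and PBS had 3800 and 612 regions in the better-scoring 50%, 2364 and 540 summits in both replicates, 2583 and 783 regions at IDR at or under 0.05, and 1970 and 451 at 0.01. With a replicate left out they had 2833 to 9758 and 687 to 723 summits, and the doxorubicin list of PBS length had 1225 regions. The share of PBS regions found with doxorubicin was above chance under each setting, from 60% (50% reciprocal overlap) to 92.9% (without replicate 2). The share of doxorubicin regions found in PBS was 9.67% with 50% reciprocal overlap, 11.1% with centres within 200 bp, 13.6% in the better-scoring 50%, 21.0% with summits in both replicates, 24.1% and 20.2% at the IDR limits, 6.68 to 22.5% with a replicate left out, and 62.3% with the list of PBS length. PBS summits lay in a mean of 30.2% of doxorubicin regions at IDR at or under 0.01 and 8.03% of all matched ones. Group 1 by strength (doxorubicin) was found in PBS at 59.1% with 50% reciprocal overlap and 68.6% with centres within 200 bp, since both definitions accept fewer overlaps. Summits at the same base in both replicates made up 1.27% (doxorubicin) and 0.728% (PBS), still above chance. The clustered share of PBS-only regions ranged from 23.5% to 42.8%, above that of shared regions each time. For the named regions, 56 of 72 checks under other definitions kept the presence or absence of the other treatment and 16 did not. Reciprocal overlap of 50% has no value for 1 bp summits. The promoter, motif and gene list alternatives were not run. Read depth is unknown, so weak regions missing from PBS were not detected there, which does not show that they were absent.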

Other observations

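The comparisons of windows, summit positions, widths and chromosomes were chosen after the data were examined, as were the tests of lost binding, of dense regions, of passage and of gene-dense chromosomes, and the comparisons between replicates used for the strong doxorubicin regions.

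The 1 Mb windows with the most reproducible doxorubicin regions held 5 to 9 of them, of which PBS shared 0 to 6. Over all windows PBS shared 34.8% of these regions. PBS regions overlapped 6 of the 9 at 61 to 62 Mb of chromosome 11, 4 of the 8 at 18 to 19 Mb of chromosome 19, 4 of the 6 at 36 to 37 Mb of chromosome 6 and 3 of the 6 at 5 to 6 Mb of chromosome 4. They overlapped 2 of the 6 at 35 to 36 Mb of chromosome 9, 2 of the 5 at 22 to 23 Mb of chromosome 1, 1 of the 7 at 35 to 36 Mb of chromosome 14 and 0 of the 7 at 40 to 41 Mb of chromosome 19. No test of these windows was made, and the counts are too small to rank them.

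Where p53 was found in all 4 libraries, it was found at nearly the same base. Over 497 reproducible regions with a summit in each library, the median distance was 12 bp between the doxorubicin summits, 18 bp between the PBS summits and 14 to 17 bp between treatments, so the distances between treatments fell between those within treatments. Doxorubicin regions with a PBS region were wider (median 781 bp) than those without (542 bp), and had a higher median −log10 p in the doxorubicin list (75.6 against 6.98). Among the reproducible doxorubicin regions the medians were 798.5 against 604 bp, and 80.6 against 19.1. As a share of each library's autosomal summits, chromosomes 7, 11, 15, 17, 19, 20 and 22 were higher in both doxorubicin libraries than in both PBS libraries, and 4, 6, 8, 10 and 18 were lower. Chromosome 17 held 5.20 ± 0.734% of summits with doxorubicin and 4.004 ± 0.0619% with PBS, and chromosome 6 held 5.39 ± 0.442% and 7.06 ± 0.0181% (SD, n = 2). Such a separation in 12 of 22 autosomes compares with 7.33 by chance (33.3% for 2 against 2), but shares of one library are not independent. The number was 11 at q at or under 0.01 and 15 without the clusters, where chromosomes 10, 15 and 20 no longer separated and 2, 5, 9, 12, 13 and 16 did.

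The PBS regions with no doxorubicin region fell into a clustered and a scattered part. Of the 111 clustered regions, 52.3% (43.0 to 61.3%) held a summit of doxorubicin replicate 1 and 0.901% one of replicate 2, so loss of binding under doxorubicin is not shown and, with 1 library going each way, not excluded. Another candidate explanation is signal of dense regions that varies between libraries: PBS summits lay in 64.0% of these regions in replicate 1 (54.7 to 72.3%) and 29.7% in replicate 2 (22.02 to 38.8%), and replicate 1 was the higher one with doxorubicin too. Since replicate 1 was at passage 3 and replicate 2 at passage 5 in both treatments, dense-region signal, passage and a batch shared by a replicate number cannot be told apart here. The 167 scattered regions may be calls near the detection limit. Their median mean −log10 p was 4.02 against 14.6 for shared PBS regions. Of the 167, 156 held no summit at an FDR under 0.05 in either PBS library, as did 37 of the 111 clustered regions. Lost binding at single regions among the 167 is not shown and stays open.

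Doxorubicin replicate 2 had 7394 summits (75.8%) with no replicate 1 summit within 200 bp, of which 2725 (36.9%) lay in a region matched between the replicates at the relaxed threshold. Whether passage acts alike in both treatments cannot be told: PBS replicate 2 had 1.05 times the summits of replicate 1 (0.947 to 1.17, counting error only), but this is 1 library per passage at unknown depth. Greater sensitivity of the replicate 2 library may contribute, since the summits in replicate 2 alone were weak (median −log10 q 5.39 against 36.5 for those in both) and 98.2% of its 1000 strongest were in replicate 1. Signal spread over chromosomes 16, 17, 19, 20 and 22, a set taken as gene-dense after the chromosome shares were seen, stays undecided: they held 22.6% of the summits in replicate 2 alone and 15.8% of those in both, but by share of autosomal summits, replicate 2 exceeded replicate 1 on 17, 19 and 22, lay below it on 20 (2.87% against 3.34%), and on 16 lay below it with the clusters (4.64% against 5.08%) and above it without them (4.64% against 4.07%).

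Of the 760 doxorubicin regions in group 1 by strength, 158 had no PBS region, and lower sensitivity of the PBS libraries could account for them if mainly the weaker ones were missing. Strength separated the regions with a PBS region from those without at an area under the curve of 0.713 (bootstrap 95% interval 0.671 to 0.756), under the 0.8 set in advance as speaking against lower sensitivity alone. As a comparison of the same size, the 760 strongest summits of 1 doxorubicin library were looked up in the other, whose list was shortened by strength until 602 were found. The area was then 0.818 (0.783 to 0.852) with strength from replicate 2 and 0.849 (0.820 to 0.878) with strength from replicate 1. A shortened list only stands in for a less sensitive library, however. In 4 pairings of replicates of the same treatment, 643 to 2833 summits were looked up. Of these pairings, PBS replicate 1 looked up in replicate 2 gave 0.747 (0.847 without the clusters) and the other 3 gave 0.832 to 0.854. The area for the doxorubicin regions thus fell on the side set in advance as speaking against lower PBS sensitivity alone. The comparisons do not settle this, because the pairing at 0.747 lay within the interval of 0.671 to 0.756. They also used summits of single libraries, whereas a PBS region had to be matched between 2 replicates. Lower PBS sensitivity, as the whole cause or a part, and binding gained under doxorubicin as a hypothesis stay open because the read depth is unknown.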
